A study of Mus musculus with 3 samples.

How the data were processed

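Single-cell suspensions from mouse colon were processed with 10x Genomics 3' v3 reagents, per the labels' protocols, for 3 libraries: germ-free mice given PBS, germ-free mice colonized with BT WT, and germ-free mice colonized with a BT mutant. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized, written by Cell Ranger 5.0.0 per the file headers. The submitters' processing notes name Cell Ranger, STAR and the genome build mm10, with no version for STAR. The rule by which barcodes were called cells, the annotation release and any doublet removal are not given in the sources used here. Each matrix has 32285 genes. Gene positions come from GENCODE vM21 on GRCm38, matched by gene identifier for all 119 genes of the text that were looked up.

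From these counts, barcodes with at least 300 genes, at least 500 UMIs and at most 25% mitochondrial UMIs were kept. The lowest barcodes held 500, 500 and 502 UMIs in the PBS, BT WT and BT mutant libraries, so the UMI minimum removed none. The libraries kept 72.2%, 79.0% and 74.9% of barcodes, with medians of 1413, 1374 and 1231 genes and 5.77%, 12.5% and 11.2% mitochondrial UMIs. Scrublet, as run in scanpy, called 1 of 4150, 106 of 8757 and 0 of 8012 barcodes as doublets (0.024%, 1.21% and 0.0%). It therefore did not work in the BT mutant library and called next to nothing in the PBS library, so doublets remain in the data. Removal at a fixed rate of 0.8% per 1000 barcodes, which took 138, 613 and 514 cells, was added as an alternative.

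Counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components, leaving out mitochondrial, ribosomal, immunoglobulin, T cell receptor and sex-linked genes. Leiden clustering used 15 neighbours, a resolution of 1.0 and all 3 libraries together. Clusters that scored for several classes or none were divided once more. Clusters were named by mean log2 level of 26 marker sets against clusters of the other compartments, with a minimum score of 1.5, at least 3 detected markers, and no other class with as many or more markers among the 10 leading genes. The markers, the 38 gene lists, the filters, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The naming rule was not: 5 versions were looked at after clusters and their counts per library were seen, and the 4 earlier ones are given as alternatives. The crypt pool also went through several definitions before the one used.

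UMIs were summed over the cells of a class in each library and divided by the sum's total (CPM). Ratios are log2 of CPM plus a pseudocount of 10. Folds are ratios of CPM without a pseudocount, with exact conditional binomial 95% intervals, and shares have exact Clopper-Pearson 95% intervals. A fold against 0 UMIs is a lower bound at a floor of 3 UMIs in the class sum. Classes entered a comparison with at least 50 cells in each library. For each list, the median log2 ratio over members with at least 20 UMIs was taken, with the number at least 1.5-fold higher or lower. Its percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins, describes these libraries only. Of the 33, 36 and 33 lists with a value in BT WT over PBS, BT mutant over BT WT and BT mutant over PBS, 14, 17 and 18 lay outside the central 95% of random lists. 2 of the 38 lists had no class with enough cells.

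Named genes were the 3 with the largest ratio in each direction in the 4 classes with the most cells in the smaller library. They needed at least 50 UMIs, at least 50 CPM in the higher library, an interval excluding 1, and at least 10% of the gene's highest CPM in another class of that library, as a guard against free RNA. The guard did not catch fat-cell genes, since the unnamed cluster that holds them has under 50 cells. From lists, the most abundant member and the member with the largest ratio (at least 30 UMIs) were named. After percentiles were seen, this was limited to the 3 primary lists and to lists outside the central 95%. Some genes that these rules named are not reported here. The primary lists were mucus products in goblet-like cells, antimicrobial genes in colonocyte-like cells and proliferation. The last was read in the crypt pool because stem and transit-amplifying-like cells numbered under 50. The mucus list shares Muc2, Tff3, Clca1, Fcgbp, Zg16, Agr2, Spink4, Sytl2, Ccl9, Bcas1 and Capn9 with the goblet markers. It is thus read partly on the genes that named the class. It also holds Muc3, a colonocyte marker, and Guca2a, a leading gene of colonocyte-like clusters 0 and 9. The antimicrobial list shares Saa1 and Lypd8 with the colonocyte markers.

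The interval calculation was tested on simulated data drawn from the libraries' own means with 200 genes altered by known folds. Between 95.3% and 96.0% of intervals covered the true ratio. Both libraries were drawn as Poisson counts from their pooled means, which the intervals assume, so such coverage checks the calculation only. The draws hold no variation between cells, sub-clusters or animals, so the detection rates that follow are for counting error alone. For colonocyte-like cells in BT WT over PBS (10389 genes), intervals lay above 1 for 85.1%, 95.2% and 100.0% of genes raised 1.5, 2 and 4 times. For goblet-like cells in BT mutant over BT WT (8562 genes) these were 61.2%, 91.9% and 100.0%.

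Alternatives were another mitochondrial limit (10% or none), at least 1000 genes per cell, doublets kept, resolutions of 0.5 and 2.0, 5000 variable genes, each library clustered on its own, pseudocounts of 1 and 50 CPM, median-ratio scaling, the mean over cells, cells thinned to 1000 UMIs, and list members with at least 1 or 100 UMIs. Added later were the fixed-rate doublet removal, the earlier naming rules, goblet-like cells called one by one (at least 2% of UMIs from goblet markers, a limit chosen after counts at several limits were seen), colonocyte-like cluster 9 alone and the goblet-like sub-clusters of cluster 12 alone. The RNA of B cell and colonocyte markers in other classes was summed after the results were seen. Xist had at most 1 UMI per library in each of the 5 classes checked (colonocyte-, goblet-, B-, T- and fibroblast-like), and Y-linked transcripts were present in all 3 libraries. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.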

Results

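Colon cells of germ-free mice were profiled by droplet single-cell RNA sequencing, in which each captured transcript carries a unique molecular identifier (UMI) and each droplet a cell barcode. The 3 groups were germ-free mice given phosphate-buffered saline (PBS), germ-free mice colonized with the wild type of a bacterial strain called BT (BT WT), and germ-free mice colonized with a BT mutant. The labels do not spell out BT, the mutation, the time after colonization or the number of animals. Each group had 1 library. The PBS library held 42003444 UMIs over 4425 barcodes, the BT WT library 55436776 over 8829, and the BT mutant library 54943483 over 8195. After filtering, 3197, 6974 and 6138 cells remained, with medians of 3670, 3826 and 3355 UMIs per cell. With 1 library per group no test could be run, so no difference below has a replicate check. Intervals are exact 95% intervals of the counts (binomial for shares, Poisson or conditional binomial for UMIs) and cover counting error only. Ratios therefore compare these libraries, and a difference between single libraries cannot be separated from one between animals, colon stretches or preparations.

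Epithelial cells made up 50.05% of the kept cells in the PBS library (48.3 to 51.8), 64.9% in the BT WT library (63.8 to 66.1) and 63.8% in the BT mutant library (62.5 to 65.0). Cells were named from marker genes, so each class is called like its type. Among epithelial cells, colonocyte-like cells, the absorptive lining cells, held 73.3% (71.1 to 75.5), 73.2% (71.8 to 74.4) and 81.4% (80.2 to 82.6) in PBS, BT WT and BT mutant. Goblet-like cells, the mucus makers, held 8.69% (7.35 to 10.2), 17.8% (16.6 to 18.9) and 3.42% (2.88 to 4.04). Stem and transit-amplifying-like cells held 1.88% (1.27 to 2.67), 0.773% (0.539 to 1.07) and 0.996% (0.710 to 1.36), with 30, 35 and 39 cells. B-like cells were 33.2% (31.6 to 34.9), 20.1% (19.2 to 21.1) and 19.2% (18.2 to 20.2) of all kept cells. T-like cells were 5.29% (4.54 to 6.12), 5.18% (4.67 to 5.72) and 2.17% (1.82 to 2.56), and fibroblast-like cells 4.54% (3.84 to 5.32), 3.08% (2.69 to 3.52) and 6.13% (5.54 to 6.76). Shares of all kept cells move with the epithelial yield. Among immune cells, B-like cells held 81.4% (79.2 to 83.5), 71.6% (69.6 to 73.6) and 78.0% (75.9 to 80.1), and T-like cells 13.0% (11.2 to 14.9), 18.4% (16.7 to 20.2) and 8.80% (7.42 to 10.3).

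These shares stand beside large gaps in depth and mitochondrial content. Colonocyte-like cells had medians of 1177, 3931 and 3294 UMIs and 9.48%, 18.2% and 17.9% mitochondrial UMIs in PBS, BT WT and BT mutant, and the mitochondrial limit of 25% removed 23.6%, 19.6% and 24.6% of all barcodes. Colonocyte-like UMIs summed to 11161449, 18222580 and 22786231 over 1173, 3313 and 3187 cells. With so low a PBS median, most of the PBS sum came from cells above it. Summed PBS levels in this class thus rest mostly on its deeper cells. At a limit of 10% the epithelial share was instead highest in the PBS library, at 31.5% against 24.3% and 27.5%, and the B-like share highest in BT WT, at 45.0% against 43.4% in PBS and 38.9% in BT mutant. Depending on the setting, the colonocyte-like share of the PBS library lay between 28.6% and 79.4% and that of the BT WT library between 0.756% and 75.5%, the lowest value coming from naming against the mean of the other clusters. The PBS value of 28.6% came with doublets kept, which added at most 1 PBS cell, so that share is not stable to new clustering or naming. Colonocyte-like cells also came from clusters that single libraries held. Cluster 0, led by Gsta1, Lypd8 and Car1, had 1075 PBS, 78 BT WT and 24 BT mutant cells. Cluster 17, led by Saa1, Slc26a3, Ifit1bl1, Aqp8, Atp12a and Cyp2d12, had 24, 2773 and 211, and cluster 3 had 57, 247 and 2081. Cluster 9, led by Car1 and Fabp2, had 15, 208 and 624. Any of these genes named in a comparison therefore also defines a cluster, and such a cluster of mostly 1 library can be that library rather than a cell type. Summed posterior Hox genes, whose level follows the position along the gut, stood at 164, 274 and 149 CPM (counts scaled to a common class total) in colonocyte-like cells of PBS, BT WT and BT mutant, and at 17.5, 50.7 and 28.1 CPM in fibroblast-like cells. Their BT WT over PBS ratio was 1.68 (1.59 to 1.77) in the former and 2.90 (1.86 to 4.68) in the latter. Hoxb13 made up most of the colonocyte-like sum, at 125, 222 and 107 CPM, and stood at 7.38, 29.6 and 9.25 CPM in fibroblast-like cells. Hoxa13 stood at 38.6, 52.0 and 41.6 CPM in colonocyte-like cells. In fibroblast-like cells it stood at 8.1, 15.9 and 15.8 CPM, level between BT WT and BT mutant. Counts of Hist1h2ap, Gsta1, Saa1, Cyp2c65, Ifit1bl1, Hspa1b, Bc1 and Bglap3 are uncertain, because these genes have near-identical copies among which the authors' counting can split reads.

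**Figure D1:**
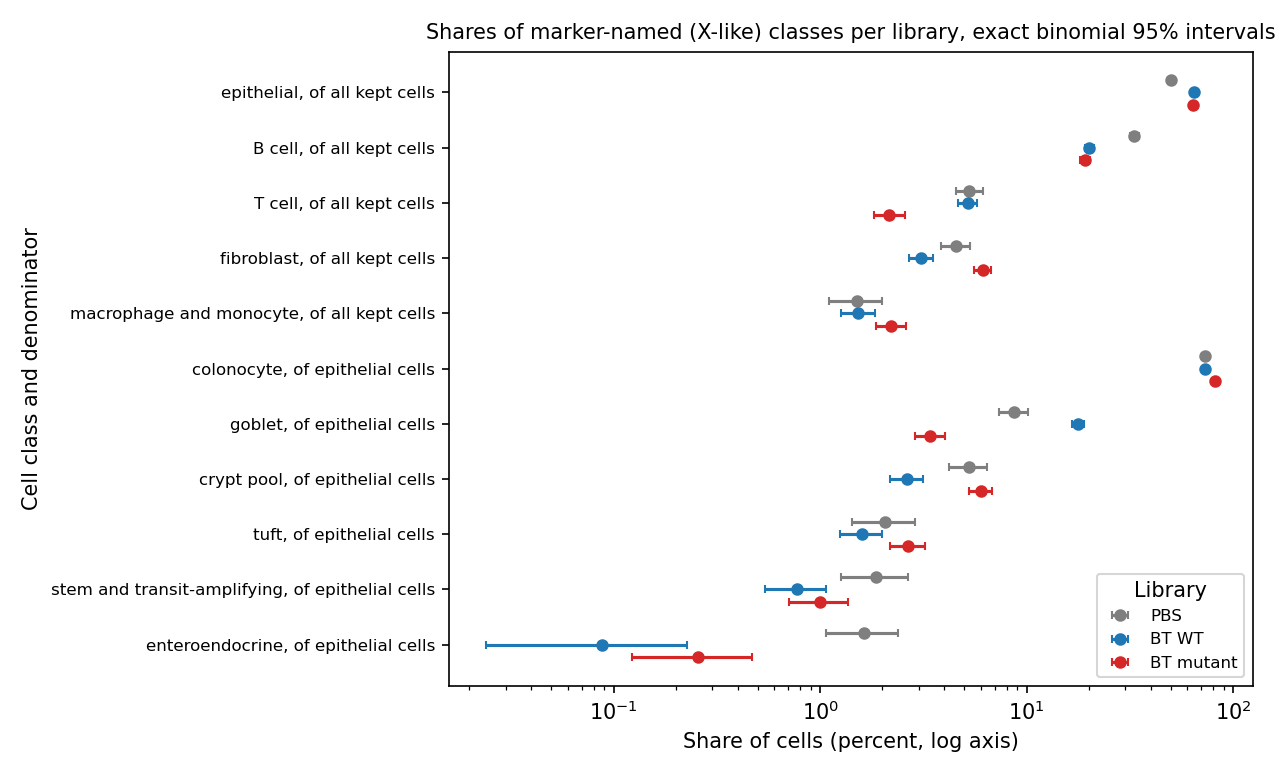
Share of cells (percent, log axis) for each marker-named class in the PBS, BT WT and BT mutant libraries, with the denominator given beside each class and exact binomial 95% intervals as bars. Goblet-like cells lie at 8.69%, 17.8% and 3.42% of epithelial cells, and B-like cells at 33.2%, 20.1% and 19.2% of all kept cells.

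The first comparison, BT WT against PBS, asks what colonization by the wild type goes with in the colon. In colonocyte-like cells, the lists for cholesterol synthesis (14 of 21 members at least 1.5-fold lower in BT WT), fatty acid use (17 of 28), oxidative phosphorylation (24 of 30), sulfide handling (11 of 18) and xenobiotic metabolism (13 of 22) had medians below 0. The interferon-stimulated (15 of 32 members at least 1.5-fold higher), NF-kB (10 of 18), tight junction (10 of 25), MHC class I (6 of 12) and clock lists (10 of 18) had medians above 0. Single genes lay far apart: Gsta1, a glutathione transferase, stood at 5.49 CPM against 932, and Ifit1bl1, a relative of the interferon-induced Ifit genes, at 393 against 10.0. The goblet-like share was 2.04 times that of PBS as reported, but not in every setting.

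Among the lists with lower medians, cholesterol synthesis had a median log2 ratio of -1.12, with 14 of 21 members at least 1.5-fold lower and 0 higher. Cyp51, a sterol demethylase, was 5.41-fold lower (4.79 to 6.12) and Insig1, a sterol sensor, 1.504-fold lower (1.40 to 1.61). Oxidative phosphorylation had a median of -0.94 with 24 of 30 members lower and 0 higher, where random lists matched on expression had a median of -0.30. In these cells the nuclear RNAs Neat1 and Malat1 stood at 4149 CPM against 1240.3 and at 69312 against 58668. Its members Cox6c and Cox7c, subunits of cytochrome c oxidase, were 3.15-fold (3.10 to 3.21) and 2.54-fold (2.496 to 2.583) lower, with log2 ratios of -0.37 and -0.25 at a mitochondrial limit of 10%. Fatty acid and PPAR targets had a median of -0.88, with 17 of 28 members lower and 3 higher. Fat-cell RNA, which includes lipid genes, moved with this list in these cells: Cfd stood at 0.384 CPM against 283 in PBS, Scd1 at 2.31 against 224, Fabp4 at 6.64 against 109 and Lpl at 3.02 against 37.0. Cyp4b1, a monooxygenase, was 27.5-fold lower (22.5 to 34.0). Sulfide and sulfur metabolism had a median of -0.68, with 11 of 18 members lower and 0 higher. Selenbp1, a methanethiol oxidase, was 3.46-fold lower (3.40 to 3.52), and Gclc, which catalyses the first step of glutathione synthesis, 16.7-fold lower (15.7 to 17.7). Short-chain fatty acid uptake and oxidation had a median of -0.54, with 8 of 18 lower and 0 higher, and Bsg, the chaperone of monocarboxylate transporters, was 2.37-fold lower (2.29 to 2.45; a log2 ratio of -0.40 at a mitochondrial limit of 10%). Aryl hydrocarbon receptor and xenobiotic genes had a median of -0.87, with 13 of 22 lower and 2 higher. Gsta1 (ENSMUSG00000074183, chromosome 9, 78230656 to 78242684 on GRCm38) was 169.8-fold lower (139 to 209), while the drug exporter Abcb1a was 1.23-fold lower (1.21 to 1.26) and turned to a log2 ratio of 0.28 when each cell weighed the same. Cbr3, a carbonyl reductase outside the lists, was 48.3-fold lower (42.9 to 54.6).

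Of the lists with higher medians, interferon-stimulated genes had a median log2 ratio of 0.55, with 15 of 32 members higher and 0 lower. Oasl2, an antiviral oligoadenylate synthetase relative, was 10.7-fold higher (7.92 to 14.8). The most abundant member, Ifi27l2b, was 1.17-fold higher (1.10 to 1.23) and turned to -0.013 under median-ratio scaling. Ifit1bl1 (ENSMUSG00000079339, chromosome 19, 34592891 to 34601956) was 39.2-fold higher (32.5 to 47.6). NF-kB and chemokine genes had a median of 0.63, with 10 of 18 higher and 0 lower, among them the feedback inhibitors Tnfaip3, 3.45-fold higher (3.10 to 3.86), and Nfkbia, 1.59-fold higher (1.51 to 1.67), whose log2 ratios of 1.54 and 0.64 were 0.31 and 0.074 at a mitochondrial limit of 10%. Tight junction genes had a median of 0.57, with 10 of 25 higher and 1 lower. Tjp1, the scaffold ZO-1, was 3.05-fold higher (2.84 to 3.27), while Cldn7 was 1.07-fold higher (1.06 to 1.09) and turned to -0.13 under median-ratio scaling. MHC class I genes had a median of 0.46, with 6 of 12 higher and 1 lower. Members went both ways: the immunoproteasome subunit Psmb8 was 7.44-fold higher (6.09 to 9.18) and the class I heavy chain H2-K1 1.45-fold lower (1.43 to 1.48). Clock genes had a median of 0.67, with 10 of 18 higher and 2 lower, Dbp being 4.35-fold higher (3.92 to 4.85) and Bhlhe40 1.43-fold higher (1.35 to 1.51). Outside the lists, Cyp2d12, a cytochrome P450, was 7.62-fold higher (7.01 to 8.29), and Mlxipl, the glucose-responsive factor ChREBP, 8.31-fold higher (7.21 to 9.62). Antimicrobial genes had a median of 0.17 with 5 of 20 higher and 4 lower. The hydrogen peroxide source Duox2 was 9.17-fold higher (7.24 to 11.8), and the acute-phase protein Saa1 had a log2 ratio of -0.039 that turned to 0.37 when each cell weighed the same. MHC class II genes had a median of -0.20, with 3 of 9 lower and 0 higher. Class II genes also lead the B-like clusters, and RNA of the 10 B cell markers, which include no class II gene, moved the same way in colonocyte-like cells, at 10.8 CPM (9.35 to 12.4) in BT WT against 63.3 (58.8 to 68.2) in PBS.

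In goblet-like cells of the same comparison, mucus and secreted products had a median of 0.19, with 7 of 22 members higher and 5 lower. Colonocyte marker RNA stood at 13885 CPM against 9805 in these cells, Malat1 at 46988 against 31958 and Neat1 at 3806 against 1812. Zg16, a mucus lectin and the most abundant member, stood at 29016 CPM against 37247 and was 1.28-fold lower (1.27 to 1.29), though at 0.21 with a mitochondrial limit of 10%, and the membrane mucin Muc1 was 5.70-fold higher (4.25 to 7.81). Muc2, the main secreted mucin, chosen after its values were seen, stood at 16902 CPM against 7814. Unfolded protein response genes had a median of -0.40, with 5 of 24 lower and 1 higher, and Atf3, a stress factor, was 2.24-fold lower (2.13 to 2.36), beside a median of -0.37 for dissociation stress genes. Cluster 12 held most goblet-like cells in 4 sub-clusters: most PBS cells lay in 1 of them (76 cells, against 30 BT WT), and most BT WT cells in the others (251, 177 and 302, against 13, 16 and 9 PBS). The sub-cluster with 251 BT WT cells had colonocyte as its next-best class, at a score of 2.16, and Ceacam1 among its leading genes. Its BT WT cells had a median of 8003 UMIs, against 4923 and 4122 in the sub-clusters with 177 and 302. Doublets with colonocytes were not excluded there. Stem and transit-amplifying-like cells were too few, so their lists were read in a crypt pool of these and unnamed crypt clusters, with 84 PBS, 119 BT WT and 235 BT mutant cells. There proliferation genes had a median of 0.032, with 0 of 30 higher and 0 lower: Hmgb2, a chromatin protein of dividing cells, had a ratio of 0.904 (0.853 to 0.958) and Cdc20, a mitotic activator, was 1.49-fold higher (1.24 to 1.80). Wnt target and stem genes had a median of 0.17, with Ccnd2, a G1 cyclin, at a ratio of 0.982 (0.909 to 1.06) and Cd44 2.12-fold higher (1.35 to 3.43), turning to -1.31 in thinned cells.

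In fibroblast-like cells, the antiviral gene Ifit1 was 11.7-fold higher in the BT WT library (7.79 to 18.3), Cmah, which makes a sialic acid form, 4.04-fold higher (2.93 to 5.68) and the collagen gene Col5a3 3.91-fold higher (2.81 to 5.55). The matrix gene Thbs4 was 11.7-fold lower (6.61 to 22.6; a log2 ratio of -2.47, and -0.95 in thinned cells), the lubricin gene Prg4 10.1-fold lower (5.26 to 21.9) and Ctla2a, a cathepsin inhibitor homologue, 25.9-fold lower (12.9 to 61.0). In T-like cells, the replication-linked histone Hist1h2ap was 3.95-fold higher (2.84 to 5.61) and the immunoproteasome subunit Psmb10 2.24-fold higher (1.61 to 3.16). The galectin Lgals1 was 2.10-fold higher (1.54 to 2.91) but turned to -0.68 at a mitochondrial limit of 10%. Bglap3 was 25.6-fold lower (11.3 to 71.4; a log2 ratio of -2.96, and -0.60 at a mitochondrial limit of 10%), Clca4a, itself a colonocyte marker, 16.7-fold lower (8.45 to 37.6) and the lipoprotein cofactor Apoc2 at least 28.4-fold lower, with a log2 ratio of -2.69 that was -1.04 without a mitochondrial limit. RNA of the 20 colonocyte markers was also lower in T-like cells, at 2010 CPM in BT WT against 4208 in PBS. RNA of other cells is therefore not excluded for these lower genes. In B-like cells, the linker histone Hist1h1b was 4.12-fold higher (3.07 to 5.62), but its log2 ratio of 1.498 was 0.34 with equal weight per cell and 0.0080 in thinned cells, and the chemokine receptor Ccr6 1.96-fold higher (1.64 to 2.35). Hist1h2ap was 1.85-fold higher there (1.67 to 2.05), turning to -0.22 when each cell weighed the same. The fat-cell genes Cfd and Car3 were at least 248-fold and at least 84.2-fold lower, against a floor of 3 UMIs, and Fabp4 12.1-fold lower (8.54 to 17.8). Cfd was also 738-fold lower (358 to 1837) in colonocyte-like cells. In the PBS library an unnamed cluster of 11 cells held Cfd at 46691 CPM, and no other library had cells in it.

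Under median-ratio scaling the median gene of colonocyte-like cells shifted by -0.24 in this comparison, of B-like cells by 0.15 and of T-like cells by 0.11. The mucus median turned to -0.11 within the sub-clusters of cluster 12, the antimicrobial one to -0.070 with libraries clustered apart and the Wnt one to -0.12 with equal weight per cell, while at a mitochondrial limit of 10% oxidative phosphorylation stood at -0.0008 and fatty acid genes at -0.17, in thinned cells MHC class II stood at -2.08, and the goblet-like share of PBS exceeded that of BT WT in 3 settings (20.4% against 18.4% with at least 1000 genes per cell).

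**Figure D2:**
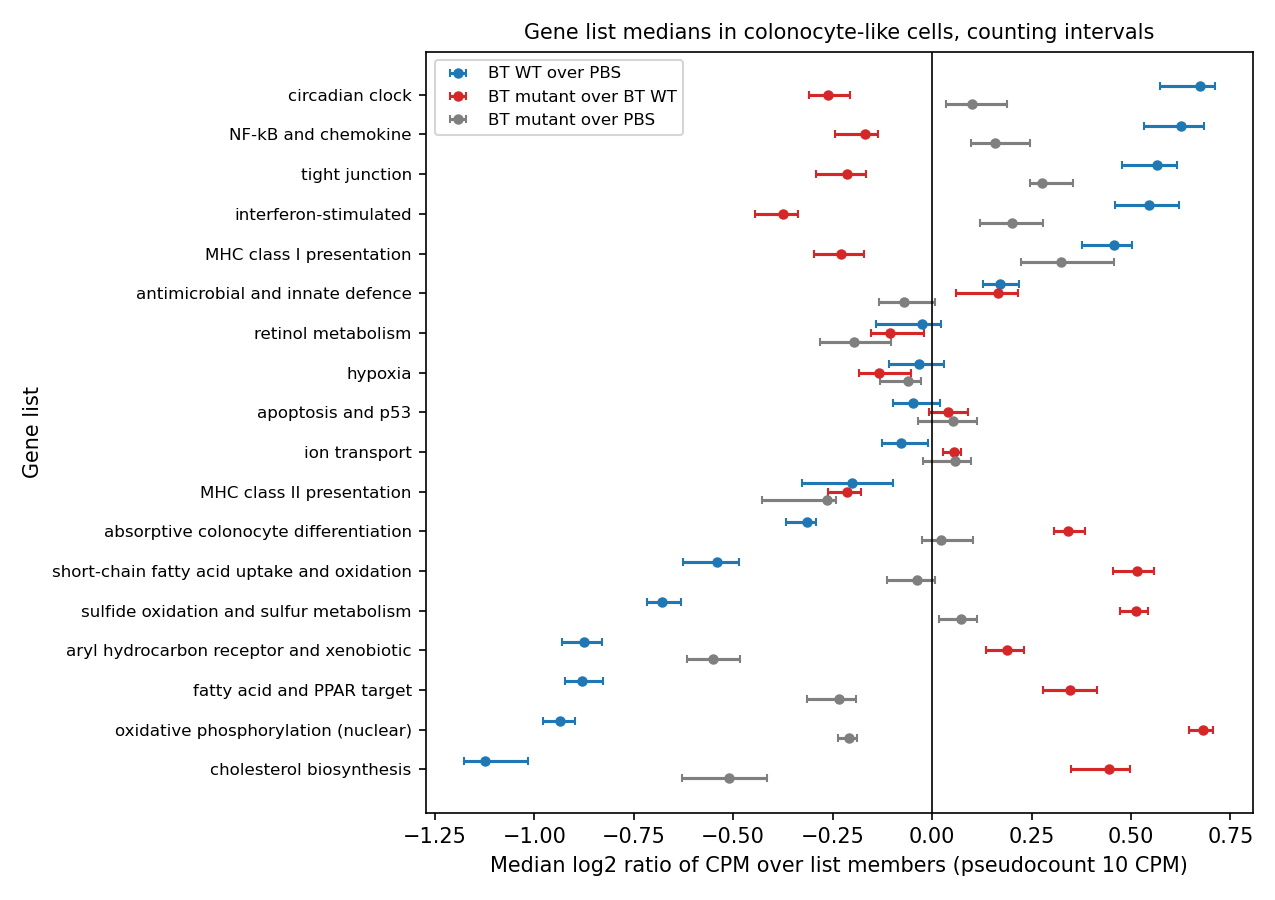
Median log2 ratio of CPM over the members of each gene list in colonocyte-like cells (horizontal axis) for the 3 comparisons, with bars for the 95% range of the median under counting error. Oxidative phosphorylation lies at -0.94 for BT WT over PBS, 0.68 for BT mutant over BT WT and -0.21 for BT mutant over PBS, and interferon-stimulated genes at 0.55, -0.37 and 0.20.

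The second comparison, BT mutant against BT WT, asks what the bacterial mutation goes with in the colon. Goblet-like cells were 3.42% of epithelial cells in the BT mutant library against 17.8% in the BT WT library, a ratio of 0.193 whose direction held in all 14 alternatives. In colonocyte-like cells, the respiratory (18 of 30 members at least 1.5-fold higher in BT mutant), sulfide (8 of 18), cholesterol (8 of 21) and fatty acid lists (7 of 27) had medians above 0, and the interferon-stimulated list (12 of 32 lower) one below 0. Fabp2, the intestinal fatty acid-binding protein, stood at 1814 CPM against 181. In goblet-like cells the resistin-like protein Retnlb stood at 1284 CPM against 38.5, while Zg16 was 3.94-fold lower, though at a log2 ratio of -0.29 within the sub-clusters of cluster 12.

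Oxidative phosphorylation had a median log2 ratio of 0.68 in colonocyte-like cells, with 18 of 30 members higher and 0 lower, against 0.19 for matched random lists, while Neat1 stood at 2262 CPM against 4149 and Malat1 at 39289 against 69312. Cox6c was 2.41-fold (2.37 to 2.45) and Cox7c 2.07-fold higher (2.03 to 2.10). Short-chain fatty acid genes had a median of 0.52 (8 of 18 higher, 0 lower), with Bsg 1.81-fold higher (1.75 to 1.86). Sulfide and sulfur metabolism had a median of 0.51 (8 of 18 higher, 0 lower), with Tstd1, a sulfurtransferase, 3.14-fold higher (2.998 to 3.287) and Selenbp1 1.48-fold higher (1.451 to 1.501). Cholesterol synthesis had a median of 0.45 (8 of 21 higher, 1 lower), with the farnesyl diphosphate synthase Fdps 3.43-fold higher (3.04 to 3.87) and the sterol carrier Stard4 1.14-fold higher (1.07 to 1.22). Fatty acid and PPAR targets had a median of 0.35 (7 of 27 higher, 1 lower). Of these, Fabp2 (ENSMUSG00000023057, chromosome 3, 122895072 to 122899506) was 10.0-fold higher (9.66 to 10.4). Outside these lists, the carbonic anhydrase Car1 was 4.55-fold higher (4.47 to 4.64) and the cytochrome P450 Cyp2c65 5.62-fold higher (5.07 to 6.23). The sugar phosphate exchanger Slc37a2 was 13.8-fold lower (12.2 to 15.6), the proton pump Atp12a 5.34-fold lower (5.11 to 5.59) and the sorbitol dehydrogenase Sord 3.32-fold lower (3.16 to 3.49).

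Interferon-stimulated genes had a median of -0.37 in these cells, with 12 of 32 lower and 0 higher. Ifit1 was 9.81-fold lower (7.57 to 12.9), and Ifi27l2b 1.07-fold higher (1.02 to 1.11), turning to -0.19 at a mitochondrial limit of 10%. Tight junction genes had a median of -0.21 (2 of 25 higher, 5 lower), with cingulin (Cgn) 1.75-fold lower (1.68 to 1.81) and Cldn7 at a ratio of 1.001 (0.988 to 1.014). MHC class II genes had a median of -0.21 (0 of 9 higher, 3 lower), which turned to 0.15 with 5000 variable genes. Ctss, the invariant chain protease, was 1.16-fold lower (1.13 to 1.19). B cell marker RNA in these cells stood at 15.1 CPM in BT mutant against 10.8. H2-Ab1 was 2.95-fold lower (2.53 to 3.44) and turned to 0.10 at a mitochondrial limit of 10%, which also put the antimicrobial median of 0.16 (3 of 21 higher, 3 lower) at -0.36. Of the antimicrobial members, Saa1 was 1.56-fold lower (1.55 to 1.57) and Zg16 9.01-fold lower (8.56 to 9.49). Zg16 is a goblet product, and goblet marker RNA in B-like cells was likewise lower in the BT mutant library, 352 CPM against 1416.

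In goblet-like cells the mucus list had a median of -0.97, with 7 of 23 members higher and 12 lower. Members such as Zg16, Muc2 and Spink4 are also markers that named these cells, and Muc3 is a colonocyte marker. Zg16 (ENSMUSG00000049350, chromosome 7, 127050156 to 127087328) stood at 7357 CPM against 29016. Retnlb (ENSMUSG00000022650, chromosome 16, 48816856 to 48818892) was 33.4-fold higher (29.0 to 38.6), the secreted Spink4 14.9-fold higher (14.4 to 15.5; 8280.3 against 554 CPM) and the metallothionein Mt3 50.9-fold higher (28.4 to 101). Atp12a, the water channel gene Aqp8 (a log2 ratio of -3.14, and -1.13 at a mitochondrial limit of 10%) and the claudin gene Cldn4 were 25.2-fold (14.7 to 47.4), 11.6-fold (8.547 to 16.03) and 6.76-fold (5.43 to 8.52) lower. Atp12a and Aqp8 also lead the colonocyte-like cluster of the BT WT library, so RNA of other cells is not excluded for them, and RNA of the 20 colonocyte markers in goblet-like cells stood at 4155 CPM against 13885. Sub-cluster 12.1, whose next-best class was colonocyte, held 15 BT mutant and 251 BT WT cells. It stays in the values given for the sub-clusters of cluster 12. The nuclear RNA Malat1 stood at 16453 CPM against 46988 in goblet-like cells and Neat1 at 1448 against 3806. Cluster 8.2, led by Spink4, Agr2, Mptx1, Muc2 and Retnlb, held 50 of the 134 BT mutant goblet-like cells and 19 of the 804 BT WT ones. Cluster 8.0, led by Mptx1 and Zg16, held 17 PBS, 25 BT WT and 1 BT mutant cells. Within the sub-clusters of cluster 12, without these 2 clusters, the mucus median was 0.12 (-0.28 in thinned cells of all goblet-like clusters), Retnlb had a log2 ratio of 3.14, Spink4 0.92 and Zg16 -0.29, against 4.74, 3.88 and -1.98 with them, Cldn4 was at -1.21 against -2.56 and Mt3 at 0.0. For Zg16 the log2 ratio was -0.96 in thinned cells. Cluster 8.3, also led by Mptx1, Spink4 and Agr2, stayed unnamed, with 40 PBS, 48 BT WT and 10 BT mutant cells. It is outside the goblet-like sums, so the Spink4 fold leaves out a Spink4-led cluster with more BT WT than BT mutant cells and depends on the naming. Muc2 stood at 15204 CPM (15007 to 15403) against 16902 (16795 to 17010). Dissociation stress genes had a median of -0.53 in goblet-like cells.

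In the crypt pool, proliferation genes had a median of -0.44, with 2 of 30 higher and 11 lower: Nusap1, a spindle protein, was 3.39-fold lower (2.54 to 4.55) and Hmgb2 1.07-fold lower (1.01 to 1.12). In thinned cells the median was 0.18 over the 11 members left and Nusap1 stood at 0.56, at levels near 1 UMI. Stress and immediate early genes had a median of -0.35 there, with the chaperones Hspa1b and Hspa8 2.37-fold (1.86 to 3.02) and 1.21-fold (1.17 to 1.25) lower. Cluster 7.4 of the pool held 21 BT WT and 101 BT mutant cells, and cluster 7.5, led among others by the cycling gene Mki67, held 32 and 47, out of 119 and 235. The crypt pool held 6.004% of epithelial cells in the BT mutant library (5.28 to 6.79) against 2.63% (2.18 to 3.14).

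The T-like share of all kept cells was 0.419 times that of BT WT (0.478 times among immune cells), a direction that turned only when each library was clustered on its own (2.88% in BT mutant against 1.98%). In T-like cells, cytotoxic genes had a median of 0.31 (6 of 13 higher, 1 lower). The chemokine Ccl5 was 1.78-fold higher (1.62 to 1.95), and the tissue-homing receptor Cxcr6 3.61-fold higher (1.97 to 6.72). That median turned in 4 settings, such as -0.15 without a mitochondrial limit, where Ccl5 was at a log2 ratio of 0.097 and Cxcr6 at 0.59. In macrophage and monocyte-like cells (107 BT WT, 136 BT mutant), resident macrophage genes had a median of 0.19 (-0.41 with libraries clustered apart), with the scavenger receptor Cd163 3.70-fold higher (3.14 to 4.38) and Apoe 1.41-fold higher (1.36 to 1.46). Both are among the leading genes of 1 cluster of this class, with Mrc1 and Ccl8, which held 4 BT WT and 32 BT mutant cells. Inflammatory monocyte genes had a median of -0.38 (2 of 18 higher, 6 lower), with the chemokine Cxcl2 1.79-fold lower (1.68 to 1.90) and the chitinase-like Chil3 17.9-fold lower (7.93 to 50.2). In B-like cells, the activity-induced regulators Crem and Nr4a3 were 5.37-fold (4.23 to 6.90) and 5.03-fold (3.87 to 6.62) lower and the sorting factor Vps37b 3.83-fold lower (3.50 to 4.20), beside a median of -0.30 for dissociation stress genes in these cells. Zfp36l2, an RNA decay factor, was 1.94-fold higher (1.78 to 2.11), Sesn1, a sestrin, 1.91-fold higher (1.62 to 2.25) and the actin regulator Arpc5l 1.86-fold higher (1.69 to 2.06). B-like cells lay in clusters 5 and 6, with 725 and 679 BT WT cells and 195 and 984 BT mutant cells.

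The fibroblast-like share was 1.99 times that of BT WT, higher in every alternative run. In these cells, matrix genes had a median of -0.35 (0 of 22 higher, 4 lower), with the protease inhibitor Timp1 2.35-fold lower (1.68 to 3.31) and the proteoglycan Dcn 1.16-fold higher (1.14 to 1.18). Niche ligands had a median of -0.29 (0 of 18 higher, 4 lower), with Wnt4 6.75-fold lower (2.92 to 18.1) and the eotaxin Ccl11 1.26-fold higher (1.19 to 1.35). The chemokine Cxcl14 was 12.02-fold (6.88 to 22.7), Spon2 3.09-fold (2.53 to 3.80; a log2 ratio of -1.47, and -0.69 in thinned cells) and Bc1 3.02-fold lower (2.25 to 4.08). Gsta3, a glutathione transferase, was 4.38-fold (3.28 to 5.95), the glycosyltransferase Galnt15 2.96-fold (2.56 to 3.44) and the scaffold Mpp6 3.37-fold higher (2.46 to 4.72), but for Mpp6 the log2 ratio of 1.45 was 0.49 in thinned cells.

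Under median-ratio scaling the median gene of colonocyte-like cells shifted by 0.14 here and that of the crypt pool by 0.11. Within cluster 9, the colonocyte-like cluster with the deepest cells, the cholesterol median was 0.013, the fatty acid one 0.060 and that of oxidative phosphorylation 0.12, while Fabp2 was at a log2 ratio of 2.25 against 3.25 over all colonocyte-like cells, Car1 at 1.07 against 2.17, Tstd1 at 0.53 against 1.58, Cox6c at 0.33 against 1.26, Cox7c at 0.30 against 1.04 and Bsg at 0.19 against 0.83.

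**Figure D3:**
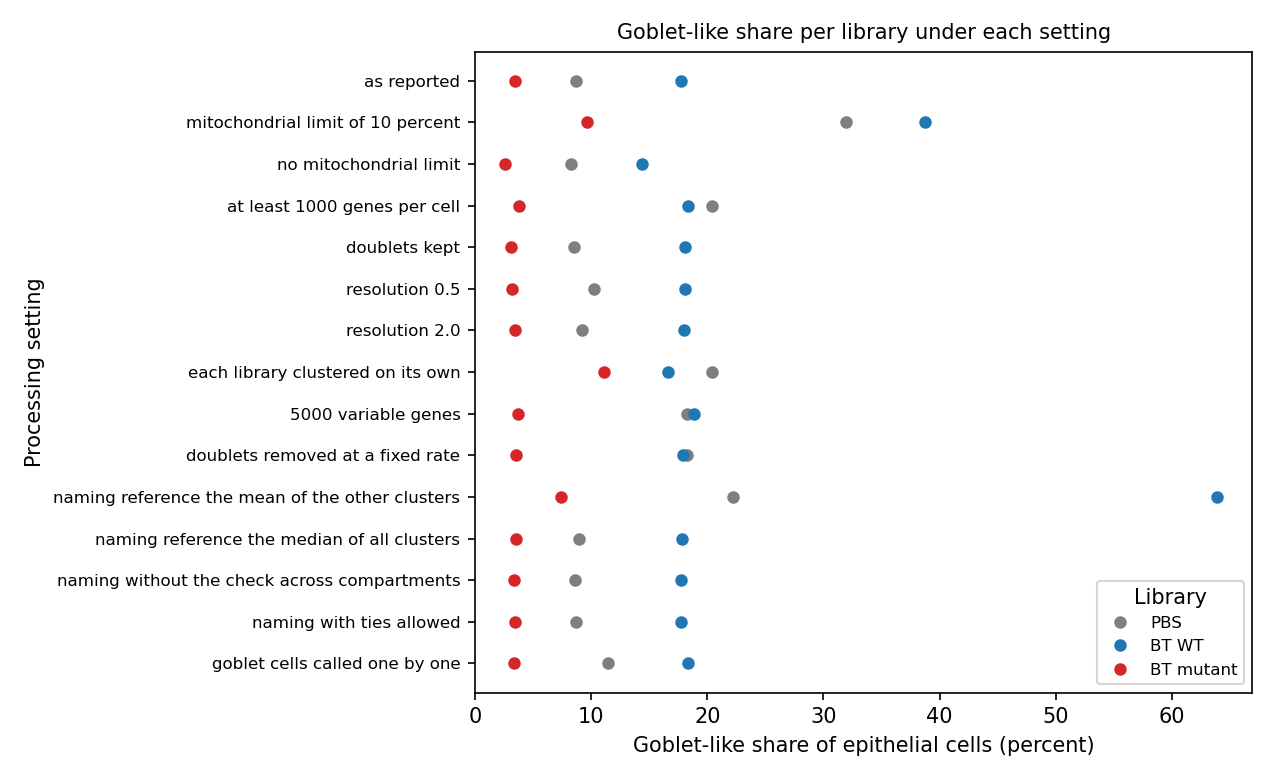
Goblet-like share of epithelial cells (percent, horizontal axis) in the PBS, BT WT and BT mutant libraries as reported and under each alternative setting (vertical axis). The BT mutant library is lowest in every setting, while PBS lies above BT WT in 3 of them, for example 20.4% against 18.4% with at least 1000 genes per cell.

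The third comparison, BT mutant against PBS, asks what colonization by the mutant goes with. Goblet-like cells were 0.394 times as frequent as in PBS, lower in all 14 alternatives, and B-like cells 0.578 times as frequent among all kept cells but 0.959 times among immune cells. In colonocyte-like cells, the xenobiotic (11 of 22 members at least 1.5-fold lower in BT mutant), cholesterol (10 of 21), fatty acid (9 of 28) and MHC class II lists (4 of 9) had medians below 0. The MHC class I (4 of 11 members at least 1.5-fold higher), tight junction (4 of 25) and interferon-stimulated lists (5 of 23) had medians above 0. Slc6a19, a neutral amino acid transporter, stood at 4.83 CPM against 303, and Slc13a1, a sulfate transporter, at 87.2 against 3.58. Retnlb in goblet-like cells stood at 1284 CPM against 79.6.

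Xenobiotic genes had a median log2 ratio of -0.55 in colonocyte-like cells (1 of 22 higher, 11 lower), with Gsta1 20.9-fold lower (19.6 to 22.3) and Abcb1a 1.92-fold lower (1.88 to 1.96). Cholesterol synthesis had a median of -0.51 (0 of 21 higher, 10 lower), with the sterol enzyme Msmo1 2.85-fold lower (2.65 to 3.06). MHC class II genes had a median of -0.27 (0 of 9 higher, 4 lower) that was -2.39 in thinned cells, with the invariant chain Cd74 4.67-fold lower (4.24 to 5.15; a log2 ratio of -1.87, and -0.60 at a mitochondrial limit of 10%) and Ctss 1.21-fold lower (1.17 to 1.24; 0.24 on the log2 scale with equal weight per cell). Cd74 leads the B-like clusters, and B cell marker RNA in these cells moved the same way, at 15.1 CPM (13.5 to 16.7) against 63.3 (58.8 to 68.2). Fatty acid and PPAR targets had a median of -0.23 (1 of 28 higher, 9 lower), yet their most abundant member, Fabp2, was 5.16-fold higher (4.99 to 5.33). Of the fat-cell genes, Scd1 stood at 5.35 CPM against 224, Fabp4 at 8.03 against 109 and Lpl at 7.81 against 37.0. Oxidative phosphorylation had a median of -0.21 (0 of 30 higher, 1 lower; 0.022 in matched random lists), with Sdhc, a subunit of succinate dehydrogenase, 1.70-fold lower (1.61 to 1.79) and Cox6c 1.31-fold lower (1.29 to 1.33). This median turned to 0.51 at a mitochondrial limit of 10%, to 0.049 without a limit and, as the fatty acid median did at 0.33, to 0.35 with naming against the mean of the other clusters. Retinol metabolism had a median of -0.20, with the retinol-binding protein Rbp2 5.32-fold (5.09 to 5.56) and the retinal dehydrogenase Aldh1a1 2.74-fold lower (2.67 to 2.81). Slc6a19 (ENSMUSG00000021565, chromosome 13, 73679745 to 73704865) was 62.8-fold lower (52.0 to 76.7), Cbr3 21.9-fold lower (20.4 to 23.6) and Cfd 1292-fold lower (553 to 3981).

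MHC class I genes had a median of 0.32 (4 of 11 higher, 2 lower). Psmb10 was 3.27-fold higher (2.97 to 3.61), and H2-K1 2.27-fold lower (2.23 to 2.31). Tight junction genes had a median of 0.28 (4 of 25 higher, 0 lower), with Tjp1 1.97-fold (1.83 to 2.12) and Cldn7 1.07-fold (1.06 to 1.09) higher, both turning below 0 at a mitochondrial limit of 10% (-0.081 and -0.0026). Interferon-stimulated genes had a median of 0.20 (5 of 23 higher, 0 lower), with the interferon regulator Irf7 3.06-fold higher (2.75 to 3.40) and Ifi27l2b 1.25-fold higher (1.18 to 1.31). The median was 0.025 with members of at least 1 UMI, and Irf7 was at a log2 ratio of 0.086 at a mitochondrial limit of 10%, against 1.39. Ifit1bl1 was 15.6-fold (12.9 to 19.0) and Slc13a1 24.3-fold higher (17.8 to 34.1). Antimicrobial genes had a median of -0.070 (6 of 20 higher, 5 lower), with Lypd8, a secreted flagella-binding protein, 1.71-fold lower (1.70 to 1.72) and Zg16 5.09-fold lower (4.81 to 5.39). Goblet marker RNA was likewise lower in BT mutant in B-like cells (352 against 1131 CPM), T-like cells (276 against 1614) and fibroblast-like cells (195 against 663).

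In goblet-like cells the mucus list had a median of -0.35, with 8 of 23 members higher and 9 lower, Zg16 being 5.06-fold lower (4.96 to 5.16). This median turned in 5 settings, such as 0.020 at a mitochondrial limit of 10%. Of these, naming against the mean of the others and the sub-clusters of cluster 12 gave the same value and are not separate checks. Muc2 stood at 15204 CPM against 7814 (7702 to 7927) in PBS, and dissociation stress genes had a median of -0.61. Retnlb was 16.1-fold (13.9 to 18.8), Plet1 15.9-fold (8.96 to 30.6) and Spink4 6.30-fold higher (6.06 to 6.56), but within the sub-clusters of cluster 12 Spink4 turned from a log2 ratio of 2.65 to -0.73, Retnlb was at 1.87 against 3.85 and Plet1 at 0.60 against 2.64. The Spink4-led cluster 8.3, left unnamed and outside these sums, held 40 PBS and 10 BT mutant cells. Gsta1 was 37.5-fold (18.1 to 93.9), Aldh1a1 12.2-fold (8.44 to 18.2) and Best2, a goblet anion channel, 10.0-fold lower (7.30 to 14.1). Gsta1 and Aldh1a1 also lead the colonocyte-like cluster of the PBS library, and were lower in colonocyte-like cells too (44.7 against 932 CPM and 439 against 1204), so RNA of other cells is not excluded for them. Colonocyte marker RNA in goblet-like cells stood at 4155 CPM against 9805, Malat1 at 16453 against 31958 and Neat1 at 1448 against 1812. Secretory specification genes had a median of 0.29 (-0.67 with libraries clustered apart), with Creb3l1, a secretory pathway factor, 3.22-fold higher (2.77 to 3.74) and Klf4, a differentiation factor, 2.84-fold lower (2.60 to 3.09), though its log2 ratio of -1.48 was -0.13 within the sub-clusters of cluster 12 and -0.48 in thinned cells. In the crypt pool, proliferation genes had a median of -0.44 (3 of 30 higher, 12 lower), with Nusap1 3.10-fold (2.30 to 4.20) and Hmgb2 1.18-fold lower (1.12 to 1.24), and 0.16 over the 9 members left after thinning. Cluster 7.4 held 12 of the 84 PBS and 101 of the 235 BT mutant cells of the pool, and cluster 7.5 held 22 and 47. Stress genes had a median of -0.20 there, with Dusp1 1.86-fold (1.68 to 2.06) and Jun 1.44-fold lower (1.39 to 1.49).

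In B-like cells, the inflammasome adaptor Pycard was 2.73-fold (2.21 to 3.39), Pxdc1 2.63-fold (2.22 to 3.13) and Arpc5l 2.45-fold higher (2.19 to 2.74). Bc1 and Car3 were 18.0-fold (11.5 to 29.9) and 43.3-fold lower (18.3 to 135), and Cfd had 1 UMI in the BT mutant library, a ratio of 0.002 (0.0 to 0.009). B activation genes had a median of 0.22, with Ighm 1.10-fold higher (1.06 to 1.13) and the antigen receptor-induced Nr4a1 2.32-fold lower (2.18 to 2.48). B-like cells of PBS lay mostly in cluster 5 (858 of 1062) and those of BT mutant in cluster 6 (984 of 1179). In T-like cells, cytotoxic genes had a median of 0.43 (7 of 16 higher, 2 lower), with Cxcr6 4.89-fold (2.29 to 11.3) and Ccl5 1.36-fold higher (1.237 to 1.503), but for Cxcr6 the log2 ratio of 1.55 was 0.032 at a mitochondrial limit of 10% and 0.40 without one. Activation genes had a median of -0.50 (1 of 9 higher, 4 lower), with Nr4a3 4.82-fold lower (3.47 to 6.86) and Cd69 at a ratio of 0.927 (0.759 to 1.13). Both genes respond to stimulation and handling, and dissociation stress genes had a median of -0.30 in these cells (1 of 23 higher, 7 lower). The cytotoxic median turned to -0.11 with at least 1000 genes per cell and to -0.60 with doublets removed at a fixed rate.

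In fibroblast-like cells, Ifit1 was 14.2-fold (9.54 to 22.2), the complement component C7 5.35-fold (3.96 to 7.40) and the interferon-induced chemokine Cxcl10 3.66-fold higher (3.04 to 4.45). The B cell attractant Cxcl13 was 7.43-fold (6.06 to 9.19), Bc1 10.6-fold (8.18 to 13.8), Prg4 21.4-fold (9.95 to 54.8; a log2 ratio of -2.42, and -0.76 in thinned cells) and elastin (Eln) 3.99-fold lower (3.41 to 4.69; a log2 ratio of -1.88, and -0.74 in thinned cells). Matrix genes had a median of -0.19, with Dcn at a ratio of 1.04 (1.02 to 1.05), and niche ligands one of -0.27, with Ccl11 1.20-fold higher (1.12 to 1.28). Dissociation stress genes had a median of -0.30 in these cells. The matrix median turned to 0.076 when each cell weighed the same. Under median-ratio scaling the median gene of colonocyte-like cells shifted by -0.14 in this comparison, of B-like cells by 0.13 and of the crypt pool by 0.10. The first and last comparisons share the PBS library, so their like-signed values are not independent.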

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

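Fixed-rate doublet removal, the 4 earlier naming rules, the one-by-one goblet call and the restrictions to cluster 9 and to the sub-clusters of cluster 12 were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. Over all alternatives that gave a value, the BT WT over PBS medians of interferon-stimulated (0.19 to 1.39), NF-kB (0.16 to 0.83), tight junction (0.33 to 0.66), MHC class I (0.14 to 0.83), cholesterol (-1.55 to -0.48), fatty acid (-1.06 to -0.17), sulfide (-0.89 to -0.28) and xenobiotic genes (-1.04 to -0.38) kept their sign. So did the BT mutant over BT WT medians of oxidative phosphorylation (0.12 to 0.81), short-chain fatty acid (0.16 to 0.64), sulfide (0.24 to 0.63) and interferon-stimulated genes (-1.14 to -0.13). The epithelial share was lowest in PBS except at a mitochondrial limit of 10%, and that of BT mutant exceeded that of BT WT there, with 5000 variable genes and with naming against the mean of the others. The goblet-like share of PBS exceeded that of BT WT with at least 1000 genes per cell, with libraries clustered apart and with fixed-rate doublet removal. The mucus medians turned within the sub-clusters of cluster 12 and with naming against the mean of the others, and that of BT mutant over PBS also at a mitochondrial limit of 10%, at a resolution of 0.5 and with 5000 variable genes. The sub-clusters of cluster 12 and naming against the mean gave the same mucus medians, so they are not separate checks. Depth limits the thinned values: 496 of 1173 PBS colonocyte-like cells were too shallow and left out, the regulatory and type 3 lists gave no thinned value in T-like cells, and in the crypt pool 6, 11 and 9 of 30 proliferation members were left in BT WT over PBS, BT mutant over BT WT and BT mutant over PBS, so no difference is read from those crypt values. Stem and transit-amplifying-like cells were not named, and gave no share, at a mitochondrial limit of 10%, with doublets kept, at resolutions of 0.5 and 2.0, with libraries clustered apart, with fixed-rate doublet removal and with naming against the mean of the others. The crypt pool gave no value in BT mutant with libraries clustered apart, nor with naming against the mean. Beyond the values listed here, 547 alternative values of single genes moved past their counting interval and 613 did not. The same held for 505 and 1216 of other list medians and for 90 and 139 of other shares. The cause was not tested for any value that moved or turned, beyond what is said below for the PBS colonocyte-like share with doublets kept. A value was counted as turned only where its interval as reported excluded no difference. Moved values of other results can therefore have the opposite sign. For example, the cytotoxic median of BT WT over PBS was 0.085 as reported and -0.75 in thinned cells. Single genes and list medians below are log2 ratios, and only values that turned, or primary values that moved past their interval, are listed.

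With 5000 variable genes, the epithelial share was 65.7% (BT mutant), the colonocyte-like share 39.2% (PBS) and 70.9% (BT WT), the goblet-like share 18.3% (PBS), and the stem/TA-like share 2.28% (BT mutant). There the mucus median was 0.34 (BT WT over PBS), -0.79 (BT mutant over BT WT) and 0.18 (BT mutant over PBS), the antimicrobial median 0.069 (BT WT over PBS), and the proliferation median -0.10 (BT WT over PBS) and -0.55 (BT mutant over PBS). Then the MHC class II median was 0.15 (BT mutant over BT WT), the ion transport median 0.018 (BT WT over PBS), and the circadian clock median -0.0045 (BT mutant over PBS). With at least 1000 genes per cell, the epithelial share was 33.6% (PBS), 67.7% (BT WT) and 61.8% (BT mutant), the colonocyte-like share 54.9% (PBS) and 78.4% (BT mutant), the goblet-like share 20.4% (PBS), and the stem/TA-like share 3.05% (PBS) and 3.02% (BT mutant). With it, the mucus median was 0.31 (BT WT over PBS) and -0.79 (BT mutant over BT WT), the antimicrobial median 0.040 (BT mutant over PBS), and the proliferation median -0.54 (BT mutant over PBS). Under it, the circadian clock median was -0.0094 (BT mutant over PBS), and the cytotoxic median -0.11 (BT mutant over PBS). At a mitochondrial limit of 10%, the epithelial share was 31.5% (PBS), 24.3% (BT WT) and 27.5% (BT mutant), the colonocyte-like share 37.0% (PBS), 41.6% (BT WT) and 61.7% (BT mutant), and the goblet-like share 32.0% (PBS), 38.7% (BT WT) and 9.65% (BT mutant). In that case, the mucus median was 0.39 (BT WT over PBS), -1.21 (BT mutant over BT WT) and 0.020 (BT mutant over PBS), and the antimicrobial median 0.45 (BT WT over PBS), -0.36 (BT mutant over BT WT) and 0.33 (BT mutant over PBS). In this setting, the NF-kB median was -0.27 (BT mutant over PBS), the ion transport median 0.084 (BT WT over PBS), the oxidative phosphorylation median 0.51 (BT mutant over PBS), the xenobiotic median -0.029 (BT mutant over BT WT), the unfolded protein response median -0.10 (BT mutant over BT WT), and the circadian clock median -0.36 (BT mutant over PBS). Here log2 ratios were Lgals1 -0.68 (BT WT over PBS), Zg16 0.21 (BT WT over PBS), H2-Ab1 0.10 (BT mutant over BT WT), Ifi27l2b -0.19 (BT mutant over BT WT), Cldn7 -0.0026 (BT mutant over PBS), Tjp1 -0.081 (BT mutant over PBS), Cox6c 0.38 (BT mutant over PBS), and Dcn -0.00040 (BT mutant over PBS). Without a mitochondrial limit, the epithelial share was 58.2% (PBS), 71.1% (BT WT) and 70.4% (BT mutant), the colonocyte-like share 79.4% (PBS), 75.5% (BT WT) and 85.0% (BT mutant), the goblet-like share 14.4% (BT WT) and 2.59% (BT mutant), and the stem/TA-like share 0.870% (PBS). Under that choice, the mucus median was 0.027 (BT WT over PBS) and -0.64 (BT mutant over BT WT), the antimicrobial median 0.062 (BT WT over PBS) and 0.060 (BT mutant over PBS), and the proliferation median -0.032 (BT WT over PBS), -0.16 (BT mutant over BT WT) and -0.28 (BT mutant over PBS). By this choice, the oxidative phosphorylation median was 0.049 (BT mutant over PBS), and the cytotoxic median -0.15 (BT mutant over BT WT). In that setting, log2 ratios were Lgals1 -0.059 (BT WT over PBS), Saa1 0.062 (BT WT over PBS), and Hmgb2 0.17 (BT mutant over BT WT). With doublets kept, which added at most 1 PBS cell, the colonocyte-like share was 28.6% (PBS). This share therefore moved by new clustering or naming of nearly the same PBS cells, not by added PBS doublets. With doublets kept, the mucus median was 0.29 (BT WT over PBS), -0.57 (BT mutant over BT WT) and -0.19 (BT mutant over PBS), the antimicrobial median 0.25 (BT WT over PBS), and the proliferation median -0.11 (BT WT over PBS). Then the ion transport median was 0.026 (BT WT over PBS), and the cytotoxic median -0.027 (BT mutant over BT WT). At a resolution of 0.5, the goblet-like share was 10.2% (PBS). With it, the mucus median was 0.31 (BT WT over PBS) and 0.015 (BT mutant over PBS), and the proliferation median -0.16 (BT WT over PBS) and -0.74 (BT mutant over PBS). Under it, the stress median was -0.043 (BT WT over PBS), the ribosome median -0.0057 (BT WT over PBS) and -0.025 (BT mutant over PBS), and the cytotoxic median -0.25 (BT mutant over BT WT). At a resolution of 2.0, the epithelial share was 47.7% (PBS). In that case, the antimicrobial median was 0.011 (BT mutant over BT WT), and the proliferation median -0.14 (BT WT over PBS) and -0.17 (BT mutant over BT WT). In this setting, the sulfide median was -0.011 (BT mutant over PBS). With each library clustered on its own, the colonocyte-like share was 45.4% (PBS) and 74.5% (BT WT), and the goblet-like share 20.4% (PBS), 16.6% (BT WT) and 11.1% (BT mutant). Here the mucus median was 0.99 (BT WT over PBS), -2.27 (BT mutant over BT WT) and -0.98 (BT mutant over PBS), the antimicrobial median -0.070 (BT WT over PBS), 0.058 (BT mutant over BT WT) and 0.084 (BT mutant over PBS), and the proliferation median -0.33 (BT WT over PBS). Under that choice, the specification median was -0.67 (BT mutant over PBS), the ion transport median 0.0099 (BT WT over PBS), the stress median -0.016 (BT WT over PBS), the Wnt median -0.011 (BT WT over PBS), the ribosome median -0.032 (BT WT over PBS), the cytotoxic median -0.82 (BT mutant over BT WT), and the resident macrophage median -0.41 (BT mutant over BT WT). With doublets removed at the fixed rate, the colonocyte-like share was 47.3% (PBS), and the goblet-like share 18.3% (PBS). By this choice, the mucus median was 0.29 (BT WT over PBS), -1.19 (BT mutant over BT WT) and -0.50 (BT mutant over PBS), the antimicrobial median 0.24 (BT WT over PBS), and the proliferation median -0.13 (BT WT over PBS) and -0.20 (BT mutant over BT WT). In that setting, the cytotoxic median was -0.60 (BT mutant over PBS). With clusters named against the mean of the others, the epithelial share was 16.1% (PBS), 17.1% (BT WT) and 18.2% (BT mutant), the colonocyte-like share 54.3% (PBS), 0.756% (BT WT) and 21.9% (BT mutant), and the goblet-like share 22.2% (PBS), 63.9% (BT WT) and 7.42% (BT mutant). There the mucus median was -0.11 (BT WT over PBS), 0.12 (BT mutant over BT WT) and 0.0042 (BT mutant over PBS). Then the fatty acid median was 0.33 (BT mutant over PBS), the oxidative phosphorylation median 0.35 (BT mutant over PBS), the unfolded protein response median -0.23 (BT mutant over BT WT), and the circadian clock median -0.066 (BT mutant over PBS). With clusters named against the median of all, the epithelial share was 62.1% (BT mutant). Without the compartment check in naming, the colonocyte-like share was 76.4% (PBS), 74.6% (BT WT) and 84.4% (BT mutant). Without that check, the antimicrobial median was 0.087 (BT WT over PBS), the retinol metabolism median 0.024 (BT mutant over BT WT), and the circadian clock median -0.0092 (BT mutant over PBS). With ties allowed in naming, the colonocyte-like share was 76.0% (PBS) and 84.0% (BT mutant). In that case, the circadian clock median was -0.0091 (BT mutant over PBS). With goblet-like cells called one by one, the goblet-like share was 11.4% (PBS). With a pseudocount of 1 CPM, the antimicrobial median was 0.29 (BT WT over PBS), and the proliferation median -0.61 (BT mutant over BT WT) and -0.59 (BT mutant over PBS). With a pseudocount of 50 CPM, the antimicrobial median was 0.052 (BT WT over PBS) and 0.038 (BT mutant over BT WT), and the proliferation median -0.20 (BT mutant over BT WT) and -0.22 (BT mutant over PBS). Under median-ratio scaling, the mucus median was -0.9997 (BT mutant over BT WT), and the antimicrobial median 0.040 (BT WT over PBS). In this setting, the sulfide median was -0.0038 (BT mutant over PBS). Here log2 ratios were Ifi27l2b -0.013 (BT WT over PBS), Cldn7 -0.13 (BT WT over PBS) and -0.034 (BT mutant over PBS), and Hmgb2 0.017 (BT mutant over BT WT). As a mean over cells, the mucus median was 0.051 (BT WT over PBS), -0.30 (BT mutant over BT WT) and -0.16 (BT mutant over PBS), the antimicrobial median 0.054 (BT WT over PBS), 0.23 (BT mutant over BT WT) and -0.28 (BT mutant over PBS), and the proliferation median -0.16 (BT WT over PBS), -0.12 (BT mutant over BT WT) and -0.29 (BT mutant over PBS). Under that choice, the sulfide median was -0.21 (BT mutant over PBS), the hypoxia median 0.069 (BT mutant over BT WT) and 0.30 (BT mutant over PBS), the Wnt median -0.12 (BT WT over PBS), the ribosome median -0.093 (BT WT over PBS) and -0.035 (BT mutant over PBS), the circadian clock median 0.0026 (BT mutant over BT WT), and the extracellular matrix median 0.076 (BT mutant over PBS). By this choice, log2 ratios were Hist1h2ap -0.22 (BT WT over PBS), Saa1 0.37 (BT WT over PBS), Abcb1a 0.28 (BT WT over PBS), Hmgb2 0.046 (BT mutant over BT WT), and Ctss 0.24 (BT mutant over PBS). With cells thinned to 1000 UMIs, the mucus median was -0.28 (BT mutant over BT WT) and -0.057 (BT mutant over PBS), the antimicrobial median -0.0046 (BT WT over PBS), and the proliferation median 0.18 (BT mutant over BT WT) and 0.16 (BT mutant over PBS). In that setting, the sulfide median was -0.34 (BT mutant over PBS), the hypoxia median 0.042 (BT mutant over BT WT) and 0.25 (BT mutant over PBS), the ribosome median -0.077 (BT WT over PBS) and -0.21 (BT mutant over PBS), and the extracellular matrix median 0.051 (BT mutant over PBS). There log2 ratios were Hist1h2ap -0.40 (BT WT over PBS), Saa1 0.20 (BT WT over PBS), Abcb1a 0.13 (BT WT over PBS), Cd44 -1.31 (BT WT over PBS), Ifi27l2b -0.10 (BT mutant over BT WT) and -0.062 (BT mutant over PBS), Hmgb2 0.18 (BT mutant over BT WT) and 0.16 (BT mutant over PBS), Nusap1 0.56 (BT mutant over BT WT), Ctss 0.13 (BT mutant over PBS), and Ccl11 -0.0062 (BT mutant over PBS). Within colonocyte-like cluster 9, the antimicrobial median was -0.038 (BT mutant over BT WT). Then the ion transport median was -0.032 (BT mutant over BT WT), and the hypoxia median 0.11 (BT mutant over BT WT). With it, log2 ratios were Ifi27l2b -0.23 (BT mutant over BT WT), Stard4 -0.17 (BT mutant over BT WT), and Selenbp1 -0.010 (BT mutant over BT WT). Within the goblet-like sub-clusters of cluster 12, the mucus median was -0.11 (BT WT over PBS), 0.12 (BT mutant over BT WT) and 0.0042 (BT mutant over PBS). Under it, the unfolded protein response median was -0.23 (BT mutant over BT WT). In that case, the log2 ratio of Spink4 was -0.73 (BT mutant over PBS). With list members of at least 1 UMI, the mucus median was 0.054 (BT WT over PBS) and -0.67 (BT mutant over BT WT), and the antimicrobial median 0.0079 (BT WT over PBS) and 0.030 (BT mutant over BT WT). In this setting, the circadian clock median was -0.0089 (BT mutant over PBS). With list members of at least 100 UMIs, the mucus median was 0.32 (BT WT over PBS) and -0.47 (BT mutant over PBS), the antimicrobial median 0.24 (BT WT over PBS), and the proliferation median -0.54 (BT mutant over PBS). Here the sulfide median was -0.10 (BT mutant over PBS).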

Other observations

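The test of cluster naming below was written after the result was seen, and the other 5 tests before their results were seen. Enteroendocrine-like cells, which make gut hormones, were 1.63% of epithelial cells in the PBS library (1.06 to 2.37), 0.0883% in BT WT (0.0241 to 0.226) and 0.256% in BT mutant (0.123 to 0.469), from 26, 4 and 10 cells. Tuft-like cells, chemosensory cells of the epithelium, were 2.06% (1.42 to 2.88), 1.59% (1.246 to 1.998) and 2.66% (2.18 to 3.21). NK and innate lymphoid-like cells were 0.719%, 1.06% and 1.03% of all kept cells, and macrophage and monocyte-like cells 1.501%, 1.534% and 2.216%. Dendritic-like cells numbered 3, 14 and 0. For 0 of 6138 cells the exact interval of the share reaches up to 0.0601%, and a floor of 3 cells is 0.0489%. Unnamed epithelial clusters outside the crypt pool held 9.06%, 4.79% and 6.23% of epithelial cells.

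The following lists had medians within the central 95% of random lists in all 3 comparisons as reported (BT WT over PBS, BT mutant over BT WT, BT mutant over PBS). In colonocyte-like cells, hypoxia genes had medians of -0.033, -0.13 and -0.060 (the last at -0.75 with a mitochondrial limit of 10%), apoptosis and p53 genes -0.047, 0.041 and 0.053, and ion transport genes -0.078, 0.054 and 0.058. In thinned cells the medians were 0.072, 0.042 and 0.25 for hypoxia and -0.17, -0.021 and -0.16 for apoptosis and p53. For ion transport they were -0.13, 0.13 and -0.14. In goblet-like cells, mucin O-glycosylation genes had medians of 0.015, 0.13 and 0.062, the latter 2 at -0.70 and -0.69 with libraries clustered apart. In T-like cells, regulatory T cell genes had medians of -0.11, 0.19 and 0.068, the first and last at -1.16 and -1.20 with fixed-rate doublet removal, and type 3 genes -0.031, 0.21 and 0.11. Ribosome biogenesis genes in the crypt pool had medians of 0.11, 0.017 and 0.092. The nuclear RNAs Malat1 and Neat1 differed between libraries in goblet-like and in colonocyte-like cells, in the latter at 58668, 69312 and 39289 CPM and at 1240.3, 4149 and 2262 CPM in PBS, BT WT and BT mutant.

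Colonocyte-like cells of the 3 libraries lay in separate clusters. After every cell was thinned to 1000 UMIs and libraries were set to 677 cells each, 72.7% of a cell's 15 nearest neighbours came from its own library (SD over 5 draws 0.785), where even mixing gives 33.3%, which argues against depth per cell as the whole cause. With only cells of at most 10% mitochondrial UMIs it was 72.7% again (SD 0.756, 188 cells each). This argues against a high mitochondrial share as the whole cause. Damage that leaves this share low was not tested. In B-like cells the share was 53.2% (SD 0.763, 1051 cells each), over 10 points lower, the outcome set beforehand against free RNA as the whole cause. It cannot decide on free RNA, because the part of each cell that is free RNA was not measured and can differ between classes. PBS colonocyte-like cells had a median of 1177 UMIs, against 3483 in PBS B-like cells. Free RNA, colonization, a batch of the single libraries, another stretch of colon (summed posterior Hox genes had BT WT over PBS ratios of 1.68 in colonocyte-like and 2.90 in fibroblast-like cells) and differences between animals stay open and could not be separated, with 1 library per group.

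The goblet-like share was lower in the BT mutant than in the BT WT library. Goblet marker RNA in B-like cells, counted without naming any epithelial cell, had a BT mutant over BT WT ratio of 0.249 (0.234 to 0.264). This lies under the bound of 0.67 set against cluster naming as the whole cause. It cannot settle the point by itself, because such RNA also depends on the marker RNA per goblet cell, which was lower for Zg16. For Muc2, at 15204 CPM against 16902 in goblet-like cells, B-like cells held 80.2 CPM against 251. Among barcodes over the mitochondrial limit, 4.45% of BT WT and 0.747% of BT mutant ones were goblet-like by the one-by-one call. Free RNA did not track the PBS share in every class: the BT WT over PBS ratio of goblet marker RNA was 1.25 in B-like, 0.675 in T-like and 3.12 in fibroblast-like cells. Another stretch of the colon stays open: summed posterior Hox genes in fibroblast-like cells had a BT mutant over BT WT ratio of 0.556 with an interval of 0.402 to 0.766, from 73 and 89 UMIs, that spans the bound of 0.67, and in colonocyte-like cells the ratio was 0.543 (0.519 to 0.567). Hoxb13 carried most of this, at 9.25 against 29.6 CPM in fibroblast-like and 107 against 222 in colonocyte-like cells. Hoxa13 was level in the former (15.8 against 15.9 CPM) and stood at 41.6 against 52.0 in the latter. Candidate explanations are a difference in goblet cells tied to the bacterial mutation, libraries from unlike stretches, and differences between animals or preparations. With 1 library per group these data cannot choose between them, and a contribution of cluster naming is not excluded.

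B-like cells of the PBS library lay mostly in another cluster than those of the BT mutant library, and Nr4a1, which responds to stimulation and to handling, was lower in B-like cells of BT mutant than of PBS. Stress and immediate early genes had BT mutant over PBS medians of -0.20 in B-like, -0.30 in T-like and -0.30 in fibroblast-like cells. All 3 share a sign, but the first is smaller than the bound of 0.3 set for handling stress of the whole library, and the others are at it, so the test was undecided. Handling may thus contribute to part of this separation, and a biological difference tied to colonization is untested.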
